A study of Mus musculus with 16 samples.

How the data were processed

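Total RNA was measured on 16 Affymetrix mouse exon arrays, 4 each from wild type brain, double knockout brain, wild type spinal cord and double knockout spinal cord. The embryos were of the CD1 strain, an outbred mouse stock, at embryonic day 18.5. Per the labels' protocols, RNA was extracted with Trizol and labelled with biotin by Affymetrix's sense target method. The design text gives 1 array to each biological replicate. Group and replicate number were taken from the sample titles.

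The deposited values are linear intensity values per probe set, from 3e-05 to 57832.67, and were made with Affymetrix Power Tools and PLIER on genome build mm8, per the submitters' processing notes. PLIER combines the probes of a probe set into 1 value. Tool versions and PLIER's settings are not given in the sources used here. The deposited values cover 625534 probe sets. The platform annotation pairs 303629 of them with 1 gene symbol and 5892 with several, and 316013 are unnamed here. Gene names and exon results rest on the probe sets with 1 symbol. Those probe sets carry 21634 symbols, of which 17657 are current in the RefSeq gene table of assembly GRCm38.p6, 3964 match it as an older synonym and 13 were unmatched, and symbols are printed as the annotation gives them. Positions of probe sets in their genes, and detection calls, were not used here, so a probe set is given by its identifier and not as a named exon.

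All values were taken as log2(intensity + 16), so that a log2 change understates the change of dim probe sets. A floor was set at the median of the mean log2 values of all probe sets, 6.73. The level of a gene was the median over its named probe sets above the floor, with at least 3 required. This gave 14570 genes, with a median of 11 probe sets each. The exon index of a probe set was its log2 value minus the level of its gene on the same array, for genes with at least 5 probe sets above the floor, 193126 probe sets of 12340 genes in all. A changed exon index means that a probe set changed relative to its gene. Cassette exons, other starts or ends of a transcript and sequence variants under the probes can each give such a change.

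Group means were fitted over all 16 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with data.table (version 1.17.8). Adjusted p-values are limma's moderated two-sided test with Benjamini-Hochberg adjustment at 0.05 within each comparison, and a feature that passed is called higher or lower. The 4 comparisons were double knockout against wild type in brain, the same in spinal cord, the difference of these 2 changes (spinal cord minus brain), and wild type spinal cord against wild type brain. The first 2 share no array. Groups of 4 arrays count as separated where all arrays of one lie beyond all of the other, which chance gives for 2.86% of genes. The number of arrays limits the precision. In simulated brain comparisons with known changes, limma called 44 of 100 genes changed by 0.5 and 94 of 100 changed by 1 on the log2 scale. It made 9 false calls among 14570 genes, 4 of them in genes holding a changed probe set. For the exon index it called 78 of 100 probe sets changed by 1 and 97 of 100 changed by 2 among 193126, with 39 false calls, 28 of them in genes holding a changed probe set. The simulated spread was drawn independently for each gene and probe set. It held no correlation between genes, no pairs of arrays and no outlying arrays, so these rates may not hold for the real arrays.

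The comparisons, tests, gene lists, named genes and alternative settings were fixed before the data were examined, apart from those named in the closing parts as chosen later. Named genes are Nova1 and Nova2, the 10 largest rises and 10 largest falls per comparison among called and separated genes (predicted clone genes skipped), up to 4 members of each list by adjusted p, the 10 probe sets with the largest rise and fall per exon comparison, 1 per gene, and up to 12 targets. The 24 gene lists were Nova splicing targets from the literature, RNA-binding splicing regulators, pan-neuronal, synaptic vesicle and release, glutamatergic, inhibitory, motor neuron and cholinergic, telencephalon and cortex, Hox, neural progenitor, cell cycle, astrocyte, oligodendrocyte and myelin, microglia and macrophage, endothelial, erythroid, skeletal muscle, cartilage and bone, fibroblast and meninges, Schwann and dorsal root ganglion, choroid plexus, hypoxia, p53 response and immediate early genes. Lists were tested on gene levels with camera of limma at a preset correlation of 0.01 between genes, which compares a list with all other genes, with Benjamini-Hochberg adjustment over the lists of a comparison. The number of target genes with a called probe set was set against 10000 random lists matched on the number of probe sets. Lists of immature neuron, midbrain and hindbrain, and imprinted genes were added later for the closing parts and adjusted over these 3. List scores are means of the log2 levels of a list's members on an array.

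Sex was read from Xist and Y-linked genes. The wild type brains were 2 female and 2 male, the double knockout brains 4 female, the wild type cords 2 female and 2 male, and the double knockout cords 3 female and 1 male. Replicate numbers in the titles are shared by the groups. Deviations from the group means of wild type and double knockout brains with the same number correlated at r = 0.212, 0.407, 0.354 and 0.272 across genes, so the brain arrays were taken as paired by number, a pairing seen in the data and not stated in the labels. Fits with that block are given beside brain results where they end a call.

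Alternatives were a minimum change of 1 on the log2 scale, pseudocounts of 1 and 64, no floor, a floor at the 75th percentile, means over probe sets, quantile normalization, a trended prior, a sex term, arrays of 1 tissue only, the replicate block, diffSplice of limma for exons, an estimated correlation in camera, fry for the lists, and leaving out each array in turn. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.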

Results

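Gene and exon levels were measured in brain and spinal cord of CD1 mouse embryos late in gestation. The embryos were wild type or lacked both Nova1 and Nova2, neuronal RNA-binding proteins that regulate alternative splicing. Each of the 4 groups held 4 exon arrays. Median intensities ran from 72.3 to 82.9 on the brain arrays and from 99.5 to 116.2 on the spinal cord arrays. The lowest correlation of gene levels between arrays of the same tissue, over both genotypes, was 0.9445 in brain and 0.9294 in spinal cord.

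The targeted genes were read first on every array. Nova1 fell by 5.03 on the log2 scale in double knockout brain (SE 0.171, adjusted p = 2.44e-13, n = 4 per group) and by 5.31 in spinal cord (adjusted p = 8.94e-14). Its level was 10.27 ± 0.315 in wild type and 5.24 ± 0.41 in double knockout brain (SD, n = 4), and 11.69 ± 0.175 and 6.38 ± 0.11 in spinal cord. The double knockout levels lay below the floor of 6.73, the median of all probe sets, so the fold is given only against that floor, at least 11.6-fold in brain and 31.1-fold in cord. All 8 Nova1 probe sets were lower in both tissues, with the arrays of the genotypes separated. Nova2 fell less, by 0.75 in brain (1.68-fold, adjusted p = 0.00162) and by 1.14 in spinal cord (2.21-fold, adjusted p = 2.43e-06). Its level in double knockout stayed above the floor, at 7.91 in brain and 7.32 in spinal cord. Of its 16 probe sets, 14 were lower in brain and 16 in spinal cord, 11 of them separated in each tissue. Those lower in brain include probe set 4551019, which changed by only -0.006. Which exons the alleles delete is not given in the sources used here, so probe sets outside the deleted part check nothing.

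**Figure D1:**
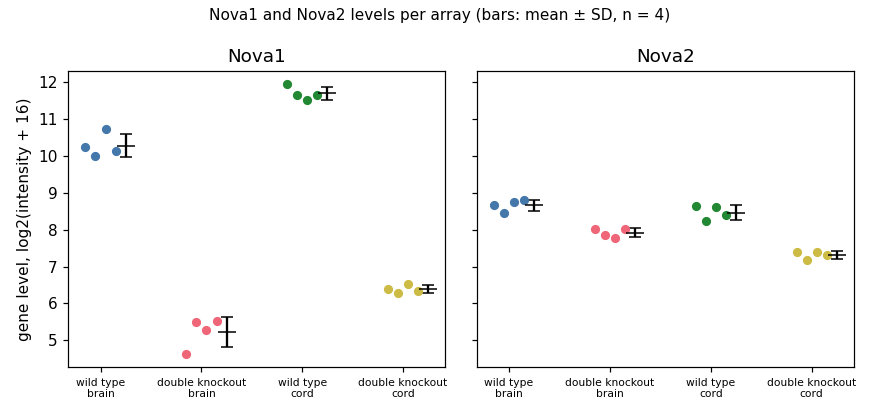
Levels of Nova1 and Nova2 (log2 intensity, y axis) on each of the 16 arrays by group, with group means and SD as bars. The 4 double knockout arrays lie below the 4 wild type arrays for both genes in both tissues, with mean changes of -5.03 and -5.31 for Nova1 and -0.75 and -1.14 for Nova2.

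The first comparison asked which genes change their level in brain when both Nova genes are lost. In double knockout brain the sodium channel gene Scn9a rose by 1.29 (SE 0.194, adjusted p = 0.00223) and was higher at 28 of its 31 probe sets. Cpne3, which encodes a calcium-dependent phospholipid-binding protein, rose by 1.21 (adjusted p = 6.29e-07), and Atg4a, an autophagy protease, by 1.20 (adjusted p = 2.45e-05). After Nova1, the largest falls were those of Dlg3, a scaffold protein of synapses (-1.61, SE 0.0923, adjusted p = 2.06e-09), and Dzip1, a zinc finger protein of the primary cilium (-1.47, adjusted p = 1.62e-06). Further falls were those of Rasgrp2, an activator of Rap proteins (-1.03), the kinase gene Lmtk3 (-1.02), Mtap2, which encodes the dendritic microtubule protein MAP2 (-1.0), and Dtd1 (-0.96). The bicarbonate transporter genes Slc4a3 (-0.89) and Slc4a10 (-0.85) and the immune recognition gene Pglyrp1 (-0.84, adjusted p = 0.00249) also fell.

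Smaller rises were those of the syntaxin gene Stx2 (0.90, adjusted p = 0.00253), the imprinted gene Mest (0.67) and the centrosomal gene Cdk5rap2 (0.61, adjusted p = 0.00591). The others were Gipr, which encodes an incretin receptor (1.16, adjusted p = 0.0323), the epithelial adhesion gene Epcam (0.65, adjusted p = 0.0322) and the collagen receptor gene Ddr1 (0.51, adjusted p = 0.0138). The last 3 calls lay near the threshold, and each ended in 5 of 8 fits without 1 array, with its direction kept. The call of Gipr ended without wild type brain 1 or 4 or double knockout brain 1, 2 or 4 (adjusted p from 0.0516 to 0.122). That of Epcam without wild type brain 1 or 4 or double knockout brain 1, 3 or 4 (0.0743 to 0.145) and that of Ddr1 without wild type brain 2 or 4 or double knockout brain 1, 2 or 3 (0.05 to 0.0825). With the replicate block the adjusted p of Epcam was 0.0604. With a sex term it was 0.161 for Epcam and 0.0537 for Gipr; the double knockout brains were 4 females and the wild type brains 2 females and 2 males. Over all alternatives adjusted p reached 0.311 for Gipr and 0.098 for Ddr1, and 1 for Epcam without a floor, where its rise was 0.18. In RefSeq gene order, counted over tested genes only, Pglyrp1 lies 2 genes and Gipr 11 genes from Nova2. All distances from Nova1 and Nova2 given here are counted in this way, so untested genes in between are left out. With the 8 brain arrays alone the calls of Cdk5rap2 (0.077), Slc4a10 (0.0516) and Pglyrp1 (0.0518) ended, each at its highest over all alternatives. The call of Mtap2 rests on the median over its probe sets, and with means it was -0.31 (adjusted p = 0.329).

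In all, limma called 39 of 14570 genes in brain, 11 higher and 28 lower, with 776 at an unadjusted p under 0.05. The genotypes were separated for 38 of the 39. Of all genes tested 4% were separated, against 2.86% by chance.

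Inhibitory, synaptic vesicle, glutamatergic and target lists were lower and the Hox list higher in double knockout brain at the preset correlation, and none of these calls held with an estimated one. Of 17 inhibitory genes tested, which hold GABA and glycine receptors and enzymes, none passed over all genes and 4 were lower adjusted over the list alone (list adjusted p = 1.39e-05, adjusted p = 0.345 with an estimated correlation). Gabrb1 was at -0.44 and Gad1 at -0.40. Of 18 synaptic vesicle genes 1 was lower adjusted over the list alone, the active zone gene Rims1 at -0.47 (list adjusted p = 0.00117, adjusted p = 0.547 with an estimated correlation). Of 14 glutamatergic genes 1 was lower adjusted over the list alone, the receptor gene Gria3 at -0.42 (list adjusted p = 0.00423, adjusted p = 0.403 with an estimated correlation), and the list's call ended without wild type brain 4 (adjusted p = 0.0937). The Nova splicing targets were lower as a list (adjusted p = 7.59e-05, adjusted p = 0.547 with an estimated correlation), but Nova1 is a member and the only 1 of 31 called, with a list median of -0.06 and a mean of -0.23. Of 27 Hox genes, which pattern the hindbrain and spinal cord, 3 were higher adjusted over the list alone and none over all genes (median 0.33, list adjusted p = 4.09e-06, adjusted p = 0.403 with an estimated correlation). Of the 27, 8 lay below the floor of 6.73 in both brain groups and 6 in 1 of them, so their changes are among signals not shown to be above background. Without the 8, the mean of the remaining 19 was 0.38. The Hox scores of the wild type brains ran from 6.18 to 7.25 and those of the double knockout brains from 7.0 to 7.33. Without both brain arrays of number 3 the list means were -0.21 for inhibitory and 0.54 for Hox genes, against -0.12 and 0.35 with all arrays.

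The other lists were not called in brain. Adjusted p was 0.302 for splicing regulators (2 of 30 lower, Nova1 and Nova2), 0.701 for pan-neuronal genes (1 of 14 lower, Mtap2), 0.237 for Schwann and dorsal root ganglion genes (1 of 13 higher, Scn9a), and 0.0796 for choroid plexus genes, which reached 0.0371 with the replicate block. It was 0.302 for microglia genes (1 of 15 higher adjusted over the list alone, Tyrobp at 0.61) and p53 response genes, and 0.603 for telencephalon, endothelial, erythroid, fibroblast, immediate early and hypoxia genes (1 of 16 hypoxia genes, Car12 at 0.45, was higher adjusted over the list alone). It was 0.799 for cell cycle genes, 0.855 for motor neuron, progenitor, astrocyte, oligodendrocyte and muscle genes and 0.878 for cartilage genes. Splicing regulators had a positive median (0.01) and a negative mean (-0.16), and pan-neuronal genes a positive median (0.03) and a negative test. Astrocyte genes had a negative median under a positive test, cartilage genes a negative mean under a positive test, and motor neuron genes a positive median (0.04) under a negative test. Both brain arrays of number 3 were low in telencephalon genes, with scores of 7.96 and 8.52 against means of 9.57 and 9.56 for the others of their groups. Leaving out both gave calls of Schwann and ganglion (adjusted p = 0.00302) and choroid plexus genes (0.00614), and a telencephalon mean of -0.01 in place of 0.13. Leaving out wild type brain 3 gave calls of telencephalon (adjusted p = 0.0152), choroid plexus (0.0152), Schwann and ganglion (0.00262) and splicing regulator genes (0.0495). Leaving out double knockout brain 3 gave calls of telencephalon (0.00666) and choroid plexus genes (0.0362), and leaving out double knockout brain 2 of Schwann and ganglion (0.0191) and choroid plexus genes (0.0484).

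The second comparison asked the same of the spinal cord. More genes were lower than higher in double knockout cord, 663 against 157 of 820 called. The largest fall after Nova1 was that of Dtd1, an enzyme that removes D-amino acids from tRNA (-1.71, adjusted p = 6.44e-08), followed by Rassf4 (-1.69, SE 0.148), Rwdd2a (-1.66, SE 0.137), the alpha-tubulin gene Tuba4a (-1.61) and Lynx1, a modulator of nicotinic receptors (-1.58). Dzip1 (-1.57), Rasgrp2 (-1.55), the chemokine gene Cx3cl1 (-1.46, adjusted p = 4.9e-07) and Syt2, a calcium sensor of vesicle release (-1.46, adjusted p = 4.49e-05), also fell. Scn9a rose by 1.26 (adjusted p = 0.000554), Cpne3 by 1.12 (adjusted p = 6.37e-07) and Atg4a by 0.90 (adjusted p = 0.000202). Sox11, a transcription factor of immature neurons that lies 50 genes from Nova1, rose by 0.85 (SE 0.154, adjusted p = 0.00244), and the RNA-binding gene Rbm12b by 0.81 (adjusted p = 0.00337; 0.18 with the floor at the 75th percentile, adjusted p = 0.590, its highest over all alternatives). Ankar rose by 0.75 (adjusted p = 0.0153), a call that ended without double knockout cord 2 or 3 (0.0564 to 0.0686) and had the opposite sign without a floor (-0.05).

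The size of this count moved with single arrays and with scaling. It was 540 without wild type cord 3, 1231 without wild type cord 4, and 425, 425 and 420 without double knockout cords 2, 3 and 4. Of all genes 11.5% were separated, against 2.86% by chance, and the median change of all genes was -0.03. Quantile normalization gave 1620 calls, 27.8% of them higher, against 19.1% here. Skeletal muscle scores ran from 7.57 to 9.70 in wild type and from 7.36 to 9.06 in double knockout cords, and without the 4 arrays over 8 (wild type 1 and 4, double knockout 2 and 4), left out after the data were seen, 100 genes were called. The call of Sox11 ended there (0.118, its highest over all alternatives), and that of Ankar (0.137; 0.879 at most over all alternatives). The rise of Rbm12b was 0.44 with means over probe sets.

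Astrocyte and inhibitory genes had the lowest means among the lists called in double knockout cord. Of 13 astrocyte genes 8 fell (9 adjusted over the list alone; list adjusted p = 1.54e-06, adjusted p = 0.236 with an estimated correlation), among them the lipid carrier gene Apoe, 31 genes from Nova2 (-0.73, adjusted p = 0.00203), S100b (-0.71), the glycolytic gene Aldoc (-0.59) and the glutamine synthetase gene Glul (-0.55). Of 17 inhibitory genes 8 fell (9 adjusted over the list alone; list adjusted p = 1.54e-06, adjusted p = 0.208 with an estimated correlation), with the glycine receptor gene Glrb at -0.84 (adjusted p = 0.000154) and the GABA receptor genes Gabra5 (-0.59), Gabrb1 (-0.56) and Gabra3 (-0.43). Of 18 synaptic vesicle genes 5 fell (9 adjusted over the list alone; list adjusted p = 1.13e-05, adjusted p = 0.323 with an estimated correlation), among them Cplx1 (-0.86, adjusted p = 8.87e-05), Sv2b (-0.57), Syp (-0.50) and Syn2 (-0.43). Of 31 Nova splicing targets 7 fell and none rose (11 lower adjusted over the list alone; list adjusted p = 0.000327, adjusted p = 0.455 with an estimated correlation), Nova1 itself among them with Epb4.1l3 (-0.59), Mapk9 (-0.60) and Aplp2 (-0.45).

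Oligodendrocyte and microglia lists were also lower in double knockout cord. Of 13 oligodendrocyte genes 3 fell (4 adjusted over the list alone; list adjusted p = 0.00486, adjusted p = 0.323 with an estimated correlation), the lineage genes Olig1 (-0.83, adjusted p = 5.35e-05), Pdgfra (-0.62) and Cspg4 (-0.57), which mark precursor cells. Of 15 microglia genes 5 fell (8 lower and 1 higher adjusted over the list alone; list adjusted p = 0.00276, adjusted p = 0.425 with an estimated correlation), among them the complement genes C1qb (-0.65, adjusted p = 0.0104) and C1qa (-0.70, adjusted p = 0.0108). The Hox list was higher (median 0.07, list adjusted p = 0.02, adjusted p = 0.611 with an estimated correlation) with no member called, and that call ended without wild type cord 1 (0.0981), double knockout cord 3 (0.0546) or the 4 arrays rich in muscle genes (0.124).

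The remaining lists were not called in cord. Of 14 glutamatergic genes 3 fell, Grin1 (-0.67) and Grin2a (-0.67), both NMDA receptor subunits, among them (4 lower and 1 higher adjusted over the list alone; list adjusted p = 0.101). Splicing regulators had 2 members lower, Nova1 and Nova2, and 2 higher (adjusted p = 0.101), with a mean of -0.10, a median of 0.08 and a positive test, which passed after quantile normalization (0.0173). Of 14 pan-neuronal genes Mtap2 fell by 0.89 and Dcx, a microtubule gene of migrating neurons, rose by 0.57 (adjusted p = 0.00129). In all 2 were higher and 1 lower (adjusted p = 0.561), with a mean of -0.02 (0.02 after quantile normalization) and a median of 0.03. The erythroid list had 1 of 4 lower, the heme synthesis gene Alas2 (-0.96, list adjusted p = 0.0824). The p53 response list had 1 of 12 lower, the cell cycle inhibitor gene Cdkn1a (-0.63, list adjusted p = 0.31), and the immediate early list 1 of 10, Egr1 (-0.56; 4 adjusted over the list alone, list adjusted p = 0.125). Motor neuron genes had 2 of 12 lower (adjusted p = 0.211), muscle genes 1 of 15 lower (0.354), progenitor genes 1 of 13 higher (0.191) and Schwann and ganglion genes 1 higher, Scn9a, and 1 lower (0.191). No member was called of the telencephalon (0.276), cell cycle (0.0824), endothelial (0.438), cartilage (0.799), fibroblast (0.104), hypoxia (0.455) and choroid plexus lists (0.451), the last with a median of -0.02 and a mean of 0.01 (-0.03 after quantile normalization). Adjusted over the list alone, members passing were 4 higher and 2 lower for splicing regulators, 2 and 2 for pan-neuronal genes, 2 and 1 for progenitor genes, 2 and 1 for Schwann and ganglion genes, and 3 motor neuron genes and 1 cartilage gene lower.

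Further alternatives ended calls of list members in cord. Without the 4 arrays rich in muscle genes those of Apoe, S100b, Aldoc, Glul, Gabra5, Gabrb1, Gabra3, Sv2b, Syp, Syn2, Epb4.1l3, Mapk9, Aplp2, Pdgfra, Cspg4, C1qb, Grin1, Grin2a, Dcx, Alas2, Cdkn1a and Egr1 ended, from 0.0585 for Glul to 0.491 for Grin2a, with all directions kept. Gabrb1 was at -0.34 and Grin2a at -0.26 there. The calls of Glrb, Cplx1, Olig1, C1qa and Mtap2 did not end. Means over probe sets ended the call of Mtap2 (-0.27, adjusted p = 0.0974, its highest over all alternatives), as they did in brain, and gave 0.38 for Dcx and -0.46 for C1qa. The floor at the 75th percentile ended those of Aplp2 (-0.25, 0.0912) and Mapk9 (-0.27, 0.167), and no floor those of Syn2 (-0.27, 0.123), S100b (0.133) and Egr1 (0.125). Over all alternatives adjusted p of these 5 reached 0.164, 0.167, 0.123, 0.133 and 0.272.

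Part of these calls ended when 1 array was left out, with directions kept. The calls of C1qa (adjusted p = 0.0503), Cdkn1a (0.0503) and Egr1 (0.0521) ended without double knockout cord 3. Those of Tnrc4, Tia1, Ina, Slc17a6, Nefh, Ret, Hes5, Csf1r, Tnnt1 and Ntrk2, each a member of a list above, ended without any 1 of 2 to 7 of the 8 cord arrays, with adjusted p from 0.0504 to 0.14. List calls were gained without wild type cord 1 (immediate early, 0.0237), wild type cord 3 or double knockout cord 2 (muscle, 0.0126 and 0.0121). They were also gained without wild type cord 4 or double knockout cord 1 or 3 (cell cycle, 0.0342, 0.0214 and 0.0208, and fibroblast, 0.0175, 0.0125 and 0.00287), and double knockout cord 3 (erythroid, 0.0304).

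**Figure D2:**
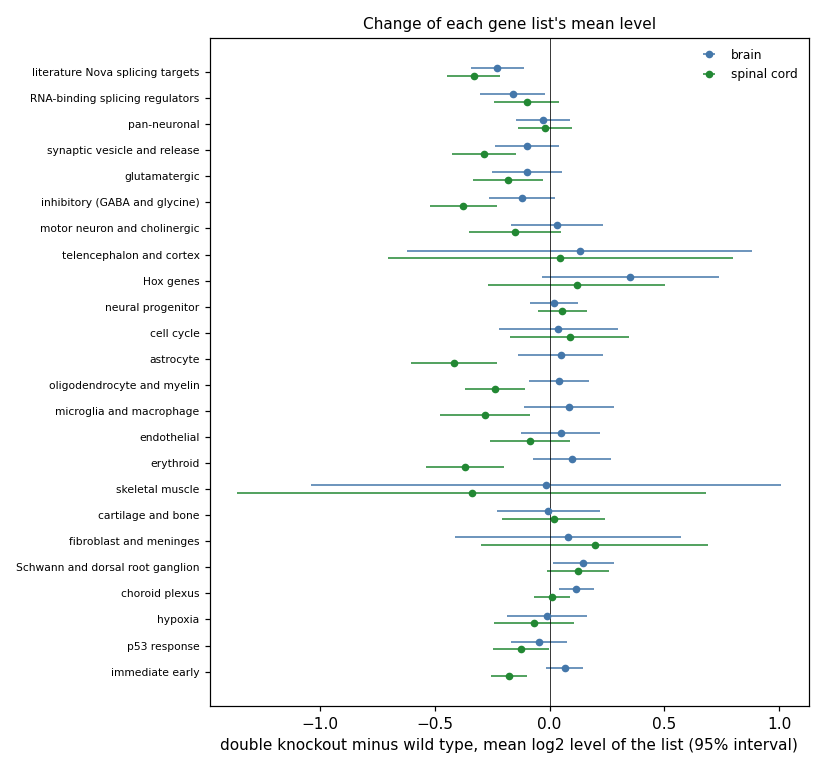
Mean log2 change of the gene lists in double knockout against wild type (x axis, log2) in brain and in spinal cord, 1 line per list, with bars for 95% intervals. Calls by camera at the preset correlation are not marked in the figure. The astrocyte and inhibitory lists lie lowest in spinal cord among lists called there, and 5 lists are called in brain and 7 in spinal cord.

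The third comparison asked whether the loss of both genes had the same effect in the 2 tissues. No single gene passed the test of the difference. The smallest adjusted p was 0.0509, for Cx3cl1, Coro6 and Syt12, whose knockout effect was lower in cord than in brain, by -1.08, -1.02 and -0.83. Nova1 (-0.27, adjusted p = 0.83) and Nova2 (-0.39, adjusted p = 0.516) did not pass either. The Nova1 level in double knockout lay below the floor in both tissues, so the sizes of its falls cannot be compared. Limma called 0 of 14570 genes, with 1166 at an unadjusted p under 0.05, and 0 with a trended prior. The count was 14 without wild type brain 3, 18 without wild type cord 4, 4 without double knockout cord 1, 1 without wild type brain 2 and 1 without wild type cord 2.

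Glial lists had the smallest adjusted p of the differences at the preset correlation, and none of the differences was called with an estimated one. The change in cord lay below that in brain for astrocyte genes (mean -0.47, list adjusted p = 2.14e-07, adjusted p = 0.228 with an estimated correlation), microglia genes (-0.37, list adjusted p = 8.47e-05, adjusted p = 0.249 with an estimated correlation) and oligodendrocyte genes (-0.28, list adjusted p = 0.000876, adjusted p = 0.228 with an estimated correlation). Adjusted over the list alone, 7 of 13, 6 of 15 and 5 of 13 members differed, Gfap (-1.18), Tyrobp (-0.98) and Olig1 (-0.68) among the 4 with the smallest adjusted p of each list. Inhibitory (mean -0.25, list adjusted p = 0.0207, adjusted p = 0.504 with an estimated correlation), synaptic vesicle (-0.19, list adjusted p = 0.0207, adjusted p = 0.723 with an estimated correlation) and erythroid genes (-0.47, list adjusted p = 0.0313, adjusted p = 0.228 with an estimated correlation) were also lower, each with 1 member adjusted over the list alone, and splicing regulators were higher (0.06, list adjusted p = 0.0207, adjusted p = 0.827 with an estimated correlation). These last 4 depended on single arrays. Splicing regulators depended on wild type brain 2 (0.0726), wild type brain 4 (0.0857), double knockout brain 3 (0.0633), wild type cord 2 (0.0992) and wild type cord 4 (0.0622). Synaptic genes depended on wild type brain 2 (0.0976) and double knockout brain 3 (0.0633), inhibitory genes on double knockout brain 3 (0.113) and wild type cord 4 (0.0766). Erythroid genes depended on wild type brain 2 (0.131), double knockout brain 3 (0.0633), wild type cords 3 (0.0527) and 4 (0.0766) and double knockout cords 1 (0.0681) and 2 (0.0572). Synaptic genes had an adjusted p of 0.0504 after quantile normalization. Without the 4 cord arrays rich in muscle genes the synaptic (0.161), inhibitory (0.26) and erythroid lists (0.113) were not called, while the fibroblast list was (mean -0.26, adjusted p = 0.0407) and had turned from 0.12 with all arrays. Its mean in cord turned from 0.20 to -0.18 (adjusted p = 0.211). Without both brain arrays of number 3 the inhibitory list was not called either (mean -0.16, adjusted p = 0.0975), while Hox (0.0022), immediate early (0.0306), target (0.0443) and motor neuron genes (0.0443) were.

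Lists without a called difference were the immediate early list (adjusted p = 0.0558; 3 of 10 lower adjusted over the list alone), pan-neuronal genes (0.302; Dcx higher adjusted over the list alone), targets (0.278) and glutamatergic genes (0.98). The others were motor neuron (0.303), telencephalon (0.638), Hox (0.677), progenitor (0.288), cell cycle (0.151), endothelial (0.302), muscle (0.638), cartilage (0.912), fibroblast (0.302), Schwann and ganglion (0.83), choroid plexus (0.677), hypoxia (0.912) and p53 response genes (0.912). The median and mean had opposite signs for pan-neuronal (-0.01 and 0.01), telencephalon (0.01 and -0.08) and cartilage genes (-0.03 and 0.02), and the Schwann list had a negative mean under a positive test. Without wild type brain 3 the differences of target (0.0222), motor neuron (0.0107), telencephalon (0.0056), Hox (0.0107) and cell cycle genes (0.00889) were called. The immediate early list was called without wild type brain 1 (0.0474), wild type brain 3 (0.0222), double knockout brain 2 (0.0348), wild type cord 1 (0.0058) or double knockout cord 2 (0.0415) or 3 (0.0191). The muscle list was called without wild type cord 3 (0.0341) or double knockout cord 2 (0.0349), and the fibroblast list without double knockout cord 1 (0.0494) or 3 (0.0124). The cell cycle list was called without double knockout brain 1 (0.0344) or 2 (0.0253) or double knockout cord 1 (0.0494) or 3 (0.0351).

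Across all genes the changes in brain and cord correlated with r = 0.421 and Spearman's rho = 0.297, where genes are not independent replicates. In both tissues 33 genes were called, 8 higher and 25 lower and none in opposite directions, where independent lists would share 0.119 and 1.27. All 39 genes called in brain had the same sign in cord, with median sizes of 0.764 in brain and 0.754 in cord. Of the 820 genes called in cord, 699 had the same sign in brain, with median sizes of 0.498 in cord and 0.145 in brain. Each set was chosen by its change in 1 tissue, which favours larger sizes there. These sizes therefore do not compare the strength of the knockout effect between the tissues. Besides the genes above, those called lower in both held the deubiquitinase gene Usp29 (-0.84 and -0.75), which lies 54 genes from Nova2, the GTPase gene Rab12 (-0.78 and -1.0), the ciliary gene Ahi1 (-0.76 and -1.0) and the imprinted gene Impact (-0.65 and -0.99). Hps5, a gene of lysosome-related organelles, was higher in both (0.47 and 0.63).

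**Figure D3:**
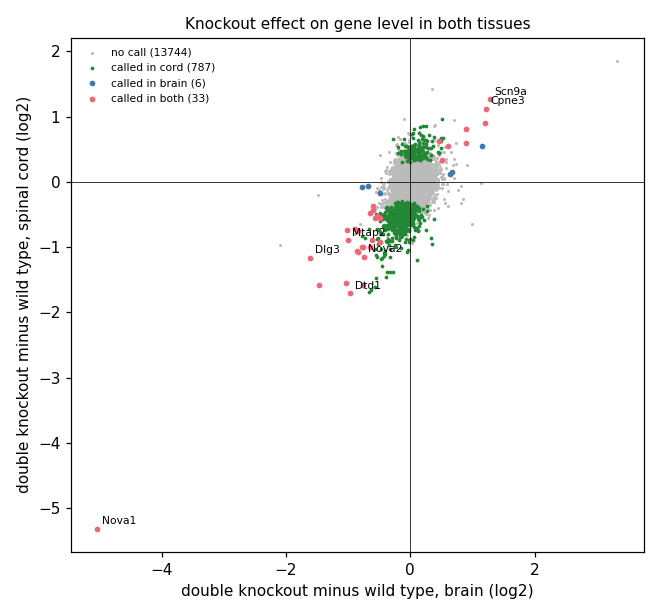
Log2 change of each of 14570 genes in double knockout against wild type in brain (x axis) and spinal cord (y axis), coloured by where the gene was called. Of the coloured genes 33 were called in both tissues, 6 in brain and not in cord, and 787 in cord and not in brain, and Nova1 lies lowest on both axes.

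The next comparison asked which exons changed relative to their gene in brain. A probe set of Ank3, the gene of the scaffold protein ankyrin-G, rose by 3.07 (probe set 5060679, SE 0.181, adjusted p = 2.44e-07). Probe sets of the glutamate receptor gene Grik2 (4489731, 2.87, adjusted p = 3.95e-07) and of Gphn, which encodes the inhibitory synapse scaffold gephyrin (4309091, 2.76, adjusted p = 1.6e-08), also rose. The Grik2 probe set lay below the floor in wild type brain (6.43). Probe sets of Aff3, a nuclear transcription regulator (5291502, -3.85, SE 0.122, adjusted p = 1.87e-10), Ptprf, a receptor tyrosine phosphatase of axons (5321146, -3.24, adjusted p = 1.23e-08), and D7Ertd715e (5139098, -2.77, adjusted p = 6.98e-07) fell. Those of the membrane skeleton gene Epb4.1l2 (4959500, -2.31), the inositol phosphate kinase gene Hisppd1 (4308081, -2.26), Aplp2, a relative of the amyloid precursor protein (5477899, -2.24), and Sorbs2 (4512395, -2.11) fell as well. A probe set of Adam22, which binds secreted LGI proteins at synapses, rose by 2.25 (4415391, adjusted p = 2.93e-06). A probe set of Dlg3 rose by 2.73 (5485223), its own log2 value going from 7.18 to 8.31 while the gene fell. Like that of Grik2, the Adam22 probe set lay below the floor in wild type brain (6.346). Those of Aff3 (6.515), Ptprf (5.349) and Hisppd1 (6.546) lay below it in double knockout brain. The sizes of these changes, that of Grik2 included, cannot be compared with the others.

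Other named changes had limits of their own. The index of a Nova1 probe set (4429841, 3.06) is no exon change, since its own value went from 8.24 to 6.26 and both it and the gene lay below the floor in double knockout. A probe set of Scfd1, which lies 3 genes from Nova1, fell by 5.70 (4847276, adjusted p = 6.12e-05), from 12.57 to 6.71, while its value in wild type cord was 7.97. Probe sets of Zfp84 (4485701, 2.47, adjusted p = 0.0169), Smarcc2 (5174790, 2.34), the adhesion gene Chl1 (5427955, 2.13) and the chromatin gene Bptf (4774487, -2.10) changed, but with the replicate block adjusted p was 0.363, 0.0745, 0.107 and 0.0877, for each the highest over all alternatives. The call of Zfp84 also ended with the 8 brain arrays alone (0.244) and without any of the 8 brain arrays apart from wild type brain 2 (0.0564 to 0.0845).

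In all, limma called 290 of 193126 probe sets in 161 genes, 132 higher and 158 lower, and 78 with the replicate block. The genotypes were separated for all 290. Of all probe sets tested 2.63% were separated, against 2.86% by chance. Of the 290, 150 changed by at least 1 on the log2 scale, 65 up and 85 down, and 42 lay in genes whose level changed 2-fold or more, 5 of them in Nova1. Without both brain arrays of number 3, left out after the data were seen, 187 were called.

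Genes known as Nova splicing targets held many of these calls. Of 31 targets tested 17 had a called probe set in brain, where random lists held 1.99 on average and 8 at most (one-sided permutation p = 1e-04, the smallest possible), and 161 of all 12340 genes had one. With the replicate block 11 did, against 0.927 on average in random lists. Nova1, whose exons cannot be read in double knockout, is 1 of the 17. Besides Ptprf, Gphn, Aplp2, Epb4.1l2 and Ank3, the others held probe sets of the microtubule plus-end genes Clasp2 (4797129, -1.99, adjusted p = 3.48e-06) and Clasp1 (5352483, -1.59, adjusted p = 3.96e-05, 0.0618 with the replicate block). Further ones were of the kinase genes Camk2g (5282948, -1.50) and Cask (4319053, -1.18), the adhesion gene Cadm1 (4974376, 1.56) and Agrn, the gene of the synapse organizer agrin (5443828, -1.05, adjusted p = 0.000523). The literature behind this list may rest in part on Nova knockout tissue, so its count is not independent evidence.

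**Figure D4:**
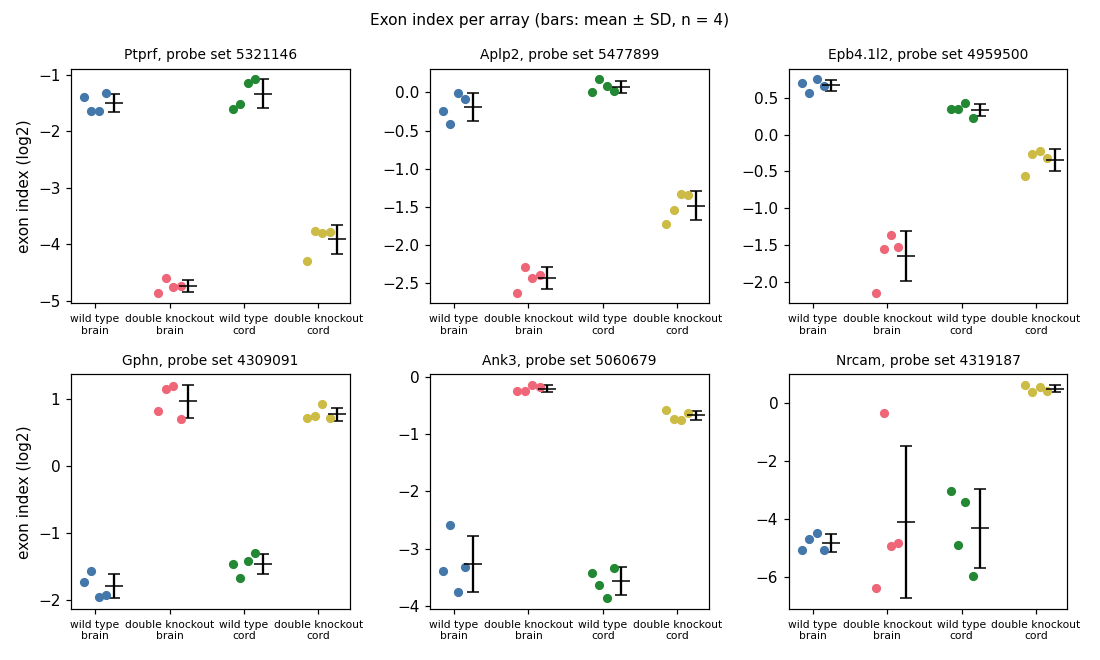
Exon index (log2 value of the probe set minus its gene's level, y axis) on each of the 16 arrays by group for probe sets of Ptprf, Aplp2, Epb4.1l2, Gphn, Ank3 and Nrcam, with group means as lines. Double knockout arrays lie below wild type for Ptprf, Aplp2 and Epb4.1l2 in brain, with mean changes of -3.24, -2.24 and -2.31, and above it for Gphn and Ank3 in both tissues.

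The same was asked of exons in spinal cord. Probe sets of Grik2 (2.95, adjusted p = 5.72e-07), the chromatin remodelling gene Smarcc2 (2.90), Ank3 (2.90, adjusted p = 9.03e-07), Adam22 (2.56) and Gphn (2.24, adjusted p = 2.97e-07) that rose in brain were called higher here too. Those of Aff3 (-2.74, adjusted p = 3.64e-08), D7Ertd715e (-2.64), Ptprf (-2.57, adjusted p = 2.78e-07) and Hisppd1 (-2.16) were again lower. Probe sets of the actin regulator Mtss1 (4555362, 2.16, adjusted p = 9.06e-07), Clasp2 (4448088, -2.09), Dlg3 (5344442, -2.05), the ubiquitin ligase gene Mid1 (5573903, -1.93) and the cadherin gene Cdh23 (5030559, -1.90, adjusted p = 8.85e-08) also changed. For Nova1 itself 6 probe sets were called here and 5 in brain, but its level in double knockout lay below the floor, so no change of its exons can be read from them.

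Further rises were those of the adhesion gene Nrcam, 2 genes from Nova1 (4319187, 4.82, SE 0.914, adjusted p = 0.031), Kidins220, 55 genes from it (4983543, 4.31, SE 0.719, adjusted p = 0.0132), and the sorting nexin gene Snx6, 16 genes from it (5413633, 3.76, SE 0.605, adjusted p = 0.0103), and Gtf2a1 fell (5495762, -4.02, SE 0.826, adjusted p = 0.0473). The values of the dimmer group were below the floor for Nrcam (5.75), Snx6 (5.79) and Gtf2a1 (5.28), so the sizes of these changes have no order. This held for 10 of the 20 probe sets taken for the size of their change in cord, and in brain for 9 of 20, among them those of Scfd1, Aff3, Ptprf and Grik2. These probe sets also varied within brain groups. The exon index of Nrcam was -0.32 in double knockout brain 2 and between -6.36 and -4.46 in the other brains, and that of Snx6 was -0.34 in wild type brain 2. The call of Nrcam ended without wild type cord 2 or 4 or any double knockout cord (0.066 to 0.0937), that of Kidins220 without double knockout cord 3 (0.0518), and that of Gtf2a1 without any 1 of the 8 cord arrays (0.0767 to 0.156). Without the 4 arrays rich in muscle genes all 4 ended (Nrcam 0.286, Kidins220 0.123, Snx6 0.159, Gtf2a1 0.404). With the 8 cord arrays alone that of Kidins220 ended (0.152), and over all alternatives its adjusted p reached 0.29.

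In all, limma called 750 probe sets in 528 genes in cord, 454 higher and 296 lower, 746 of them separated. Of all probe sets tested 5.69% were separated, against 2.86% by chance. Of the 750, 189 changed by at least 1 on the log2 scale, 119 up and 70 down, and 48 lay in genes whose level changed 2-fold or more, 6 of them in Nova1. Level changes under 2-fold can move an exon index too, so this count, like that in brain, is no upper limit. The number called in genes changed by under 0.5 is given in the closing part on processing. The count was 344, 348 and 332 without double knockout cords 2, 3 and 4, 111 without the 4 arrays rich in muscle genes and 1755 after quantile normalization.

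Of the 31 Nova targets 16 had a called probe set in cord, where random lists held 3.35 on average and 12 at most (one-sided permutation p = 1e-04, the smallest possible), and Nova1 is 1 of the 16. Besides those above, Aplp2 (-1.55), the kinase gene Mapk9 (1.76, adjusted p = 4.08e-06), the netrin receptor gene Neo1 (1.46, adjusted p = 4.11e-06), Camk2g (-1.15), Epb4.1l3 (-1.09), Cask (-0.67) and Clasp1 (-0.94, adjusted p = 0.00904) were among them. The calls of Cask and Clasp1 ended with the 8 cord arrays alone (0.0666 and 0.0815) and without the 4 arrays rich in muscle genes (0.142 and 0.277), and over all alternatives adjusted p reached 0.294 for both.

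Across probe sets the changes in the 2 tissues correlated with r = 0.18 and rho = 0.1, and 184 were called in both, 93 higher and 91 lower, where independent lists would share 0.31 and 0.242. Of the 290 called in brain 281 had the same sign in cord, and of the 750 called in cord 620 had the same sign in brain. In 15 of 108 genes with a probe set called in both tissues there were 3 or more: Mtap2 had 20 of 35, D7Ertd715e 7 of 15, Lrrfip1 7 of 25, and the presynaptic gene Rims1 5 of 43.

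The exon changes of the tissues were also set against each other. The Epb4.1l2 probe set 4959500 fell by 2.31 in brain and by 0.68 in cord, a difference of 1.63 (SE 0.191, adjusted p = 0.0468). Limma called this 1 probe set, with 10955 at an unadjusted p under 0.05, and diffSplice 434. The call ended in 13 of 16 fits without 1 array (0.0722 to 0.21), the exceptions being double knockout brains 1 and 3 and double knockout cord 1, and with the replicate block adjusted p was 0.0813. Over all alternatives it reached 0.427. Without double knockout cord 1 there were 3 calls. The fall of 0.68 in cord was called (adjusted p = 0.0404) with all arrays and not without any 1 of the 8 cord arrays (0.0505 to 0.109).

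The last comparison set wild type spinal cord against wild type brain. Hox genes, which pattern the body axis, were higher in cord, with Hoxc8 higher by 5.03 (adjusted p = 4.23e-13), Hoxb9 by 4.39, Hoxd10 by 3.94 (adjusted p = 4.73e-14), Hoxa9 by 3.76, Hoxc6 by 3.60, Hoxc10 by 3.55, Hoxb8 by 3.49 and Hoxc9 by 3.13. Ttr, a transport protein of the choroid plexus, was lower in cord by 6.01 (64.6-fold, adjusted p = 3.36e-13). Also lower were the prostaglandin synthase gene Ptgds (-3.56, adjusted p = 2.67e-09), Otx2 (-3.37), Tcf7l2 (-3.07, adjusted p = 2.22e-13), Lhx9 (-2.90), Dlx6os1 (-2.92, SE 0.431), Islr2 (-2.66), Dlx1 (-2.59, SE 0.304), Zfp238 (-2.38, SE 0.453) and Tcfap2d (-2.36). Of these, Dlx6os1, Dlx1 and Zfp238 were low in wild type brain 3. The muscle myosin gene Myl1 was higher in cord by 2.93 (SE 0.757, adjusted p = 0.00283), with an SD of 1.95 among wild type cords, and by 1.32 without the arrays rich in muscle genes. Nova1 was higher in cord by 1.42 (adjusted p = 4.11e-06; 0.85 without a floor), and Nova2 differed by -0.20 (adjusted p = 0.124). Of the 20 genes taken for the size of their change 14 were below the floor in the dimmer tissue, all 8 Hox genes above, Myl1, Otx2, Dlx6os1, Dlx1 and Tcfap2d among them, so the sizes of these changes have no order. Against the floor Hoxc8 was higher in cord by at least 15.6-fold and Hoxb9 by at least 17.3-fold.

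Limma called 8800 of 14570 genes, 3002 higher and 5798 lower in cord, with 518 changed 2-fold or more (198 up and 320 down) and 40.9% of genes separated against 2.86% by chance. The median change of all genes was -0.16, and -0.18 after quantile normalization, so that small falls of most genes lie near that shift.

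Lists of regions and of cell types differed between the tissues, and muscle and cartilage lists, which belong to neither, were higher in cord. Of 27 Hox genes 25 rose (list adjusted p = 2.77e-23, adjusted p = 0.0434 with an estimated correlation), the only list call in any comparison that held with an estimated correlation. Of 12 motor neuron genes 10 rose and 1 fell (list adjusted p = 1.8e-06, adjusted p = 0.109 with an estimated correlation), among them Ret (1.61) and the acetylcholine genes Slc5a7 (1.16) and Chat (0.86). Of 15 muscle genes 14 rose (list adjusted p = 1.44e-05, adjusted p = 0.409 with an estimated correlation), with Ckm at 2.25 and Myod1 at 1.13. The muscle scores of wild type cords 1 and 4 were 9.70 and 8.96, against 7.67 and 7.57 in the other 2. Without the arrays rich in muscle genes the list mean was 0.53 in place of 1.39 and Ckm was at 1.06. Myod1 was at 0.64 with means over probe sets, and Acan at 0.44 after quantile normalization. Of 8 cartilage genes 6 rose (list adjusted p = 0.000472, adjusted p = 0.0835 with an estimated correlation), with Runx2 at 0.81 and Acan at 0.78. Of 13 Schwann and ganglion genes 6 rose and 1 fell (list adjusted p = 0.00492, adjusted p = 0.111 with an estimated correlation), with the sensory neuron gene Prrxl1 at 2.33. All 13 telencephalon genes fell (list adjusted p = 0.00184, adjusted p = 0.48 with an estimated correlation), with Eomes at -2.06 and Lhx2 at -1.97, while wild type brain 3 was low in them. With the floor at the 75th percentile the fall of Eomes was -0.12 (adjusted p = 0.546, its highest over all alternatives). Of 11 choroid plexus genes 7 fell and 1 rose (list adjusted p = 0.0103, adjusted p = 0.0835 with an estimated correlation), with Clic6 at -1.79.

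Cell cycle genes and splicing regulators were lower in cord as lists. Of 17 cell cycle genes 16 fell (list adjusted p = 0.00179, adjusted p = 0.48 with an estimated correlation), Top2a at -0.96 and Cdc2a at -0.89. Of 30 splicing regulators 21 fell and 1 rose, Nova1 (list adjusted p = 0.00805, adjusted p = 0.48 with an estimated correlation), with Cugbp1 at -0.83 and Tnrc4 at -1.02. Of 13 oligodendrocyte genes 8 rose and 1 fell (list adjusted p = 0.0437, adjusted p = 0.48 with an estimated correlation), Cspg4 by 0.54 and Cldn11 at -0.81. Of 10 immediate early genes 4 rose (list adjusted p = 0.0398, adjusted p = 0.111 with an estimated correlation), with Npas4 at 0.58, which was 0.14 without a floor (adjusted p = 0.374, its highest over all alternatives). The oligodendrocyte call ended without wild type brain 4 (0.0552) or wild type cord 3 (0.0607), and the immediate early call without wild type brains 3 (0.0528) or 4 (0.0516), wild type cords 3 (0.0568) or 4 (0.0612) or both brains of number 3 (0.0536). After quantile normalization the splicing regulators were not called (0.313), while targets (0.000396), synaptic (0.000396), glutamatergic (0.0116) and astrocyte genes (0.00069) were called higher. With means over probe sets Tnrc4 was at -0.59.

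Members of the other lists went both ways. Of inhibitory genes 3 rose and 9 fell (list adjusted p = 0.321), the glycine genes Slc6a5 (2.13) and Glra1 (2.02) against Gabrb2 (-1.12). Pan-neuronal genes had 2 higher, the neurofilament genes Nefm (1.14) and Nefl (1.08), and 9 lower, Dcx at -1.0 among them (0.222). Glutamatergic genes had 4 higher and 5 lower (0.403), with Grin2a at 1.32 and Camk2a at -0.89, and synaptic genes 4 higher and 3 lower (0.304; 3 and 3 adjusted over the list alone). Progenitor genes had 1 higher, Hopx (1.27), and 7 lower, Hes5 at -1.55 among them (0.237). With means over probe sets Dcx was at -0.51 and Hes5 at -0.66. Astrocyte genes had 6 higher, Gfap at 1.49 among them, and 3 lower (0.051, and under 0.05 without wild type brain 1, wild type brain 3 or wild type cord 4, at 0.0356, 0.0408 and 0.0284, without both brains of number 3, at 0.0392, and without the arrays rich in muscle genes, at 0.0436). Targets had 6 higher and 10 lower (0.414), microglia genes 3 and 2 (0.237), hypoxia genes 1 and 7 (0.237) and p53 response genes 4 and 6 (0.689). Of the rest, 6 endothelial genes (4 adjusted over the list alone; 0.265) and 6 fibroblast genes (0.303) were lower and 2 erythroid genes higher (0 adjusted over the list alone; 0.13). For other called lists the counts adjusted over the list alone were the same, apart from 15 muscle and 7 cartilage genes. Targets and synaptic genes had a median of 0.03 and 0.01 with a mean of -0.03 and -0.01, which were 0.15 and 0.17 after quantile normalization, and glutamatergic (0.10 after it) and p53 response genes had negative means under positive tests.

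Exon indices differed widely between the wild type tissues. Probe sets of the monoamine transporter gene Slc18a2 (5065862, 3.73, adjusted p = 2.93e-07), the cortical transcription factor gene Tbr1 (4465153, 4.00), Tiam2 (5469025, 2.79), Eomes (5221630, 2.76) and Lsm8 (5048257, 2.70) were higher in cord relative to their gene. Lower were those of Dlx2 (5354902, -3.71), Hoxa9 (5268201, -3.20, adjusted p = 1.46e-07), Dlx5 (5066343, -2.82), Cnpy1 (4664230, -2.77), Cyb5 (5026965, -2.77), Lhx6 (4753316, -2.73) and the glutamate transporter gene Slc17a7 (4845210, -2.65). The Hoxa7 probe set 4384054 rose by 2.73, from a log2 value of 4.05 to 9.08. The 5 rises named first, and those of Otx2 (4690068, 3.59), Ptgds (4408859, 3.38) and Tcf7l2 (4416679, 3.33), are of genes whose level was lower in cord, such as Tbr1 (-2.42) and Slc18a2 (-2.04). The Otx2 probe set itself stood at 7.49 in brain and 7.70 in cord, so that its index moved with the gene. The Hoxa9 probe set went from 7.32 to 7.88 while its gene rose by 3.76. With pseudocount 64 the values were 1.20 for Hoxa7, -1.82 for Cyb5, -1.79 for Lhx6 and -1.48 for Cnpy1, and without a floor -1.65 for Slc17a7. Scfd1 (-3.88) and Kidins220 (-2.61; adjusted p = 0.0723 with the 8 wild type arrays alone, its highest over all alternatives) were lower, as was Myl1 (5088805, -2.81), a call that failed without wild type brain 1, 2 or 4 or wild type cord 1 or 4 (0.0534 to 0.0833), with a probe set value of 6.77 in brain and 6.89 in cord. Actr10 was higher (4788397, 3.32, SE 0.951; 2.19 without wild type brain 4), a call that failed without wild type brain 3 or 4 or wild type cord 4 (0.0506 to 0.0581) and with the 8 wild type arrays alone (0.105; 0.109 at most over all alternatives). The dimmer tissue was below the floor for 8 of the 20 probe sets taken for the size of their change, those of Tbr1, Hoxa7, Dlx2, Dlx5, Cnpy1, Cyb5, Lhx6 and Slc17a7. In all 42539 of 193126 probe sets were called in 10864 genes, 24016 higher and 18523 lower, 4745 of them by at least 1 on the log2 scale.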

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

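The tests of muscle RNA, sex, the share of neural tissue, strain DNA and spinal cord RNA were chosen after the results they explain were seen, while the tests of immature neurons, of midbrain and hindbrain and the other splits of the arrays were written before their results.

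Of 212 groups of 4 arrays examined, 18 held an array far from the other 3, where chance gives about 10.6. The telencephalon score was 7.964 in wild type brain 3 (others 9.482 to 9.677), 8.518 in double knockout brain 3 (9.493 to 9.608) and 7.549 in wild type cord 4 (7.824 to 7.874). Wild type brain 3 was also low in Dlx6os1 (6.588, others 9.359 to 9.693), Dlx1 (7.618, others 9.433 to 9.583) and Zfp238 (9.041, others 11.36 to 11.79), and high in Hoxd10 (6.849, others 6.281 to 6.367). Scores of Nova targets were high in wild type cord 1 (10.12, others 9.83 to 9.875) and double knockout cord 1 (9.63, others 9.57 to 9.578). The cartilage score was high in wild type cord 4 (8.525, others 8.206 to 8.238), and the immediate early score low in double knockout cord 4 (8.097, others 8.154 to 8.164). In single genes, Stx2 was at 7.78 in wild type brain 1 (others 8.218 to 8.302), Dtd1 at 9.81 in wild type brain 4 (9.519 to 9.547), and Slc4a10 at 9.305 in double knockout brain 3 (8.703 to 8.802). Tuba4a was at 8.728 (others 8.125 to 8.194) and Cx3cl1 at 9.012 (others 8.727 to 8.756) in double knockout cord 1. Ttr was at 12.87 in wild type brain 2 (others from 12.91), and Ptgds at 7.333 in wild type cord 1 (7.84 to 7.935).

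A test of the difference of the knockout effect between the tissues called the Epb4.1l2 probe set 4959500 (1.633, adjusted p = 0.0468). That call ended in 13 of 16 fits without 1 array (adjusted p from 0.0722 to 0.21). The test also called 7 gene lists: splicing regulators (0.0608), synaptic vesicle (-0.186), inhibitory (-0.254), astrocyte (-0.466), oligodendrocyte (-0.278), microglia (-0.367) and erythroid genes (-0.468). These list calls were made at the preset correlation, and with an estimated one 0 of the 7 were called (adjusted p from 0.228 to 0.827). In probe sets without a single gene symbol, which the comparisons leave out, limma called 120 of 106412 in double knockout brain (53 higher and 67 lower) and 1390 in spinal cord (989 higher and 401 lower).

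More genes were lower in the double knockout cord than in the double knockout brain. Against muscle RNA as the whole cause, 704 of the 820 calls (85.9%) were also made with the muscle score as a covariate; against sex, 673 (82.1%) were also made with a sex term. A smaller share of neural tissue would lower pan-neuronal genes with the rest, but their score changed by -0.0186 (95% interval -0.137 to 0.0993), against -0.418 for astrocyte and -0.375 for inhibitory genes. The loss of Nova itself stays open, and less mature neural tissue may contribute: a list of 19 immature neuron genes was higher in cord (mean 0.0843, p = 0.0104, adjusted p = 0.0312), though not with an estimated correlation (p = 0.104), with 1 member called (Stmn1, 0.37). Its mean was 0.06 in brain (adjusted p = 0.306), from which the cord was not shown to differ (adjusted p = 0.316), and -0.27 between the wild type tissues (adjusted p = 0.394).

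Several called genes lie near Nova1 or Nova2 in the order of the tested genes. Among the 50 nearest genes on either side of both, 9 of 200 had a call in brain, but 4 of these (Nrcam, Scfd1, Pglyrp1 and Gipr) had been named before the test and prompted it. With all named genes taken out at every place, 5 remained, 0 near Nova1 and 5 near Nova2, where random pairs of places had a median of 1 and a 95th percentile of 5 (one-sided permutation p = 0.0505). In cord 19 remained (median 15, permutation p = 0.193). DNA of another strain carried along with the targeted alleles and effects of the lost genes on their neighbours both stay open, since no sequence of these embryos was used here.

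Both brain arrays of number 3 were low in telencephalon genes. Spinal cord RNA in these samples would need Hox scores of 9.015 and 8.937, and 7.252 and 7.031 were measured, a shortfall of at least 1.76. A larger share of midbrain and hindbrain in these samples may explain the pattern, since 16 genes of those regions, 0 of them in another list, scored 8.33 and 8.334 in them, above the highest other array of each group by 0.373 and 0.344. By camera of limma that list itself did not pass in double knockout brain (mean 0.07, adjusted p = 0.392), in cord (0.08, adjusted p = 0.0776), for their difference (adjusted p = 0.316) or between the wild type tissues (-0.45, adjusted p = 0.394). No biological explanation was tested, as number 3 is no group of the design.

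Other splits of the same arrays into groups of 4 test whether chance gives as many calls. The real split, 1 of 35, gave the most calls at gene level, 39 in brain (highest other 1), 820 in cord (85) and 8800 between tissues (5975). It also did for exons, with 290 in brain (3), 750 in cord (100) and 42539 between tissues (4351). In cord and between tissues, chance alone would rank the real split first in 1 of 35 cases. The highest other split between tissues exchanged wild type brain 3 with a cord array. In brain, 8 splits part all 4 numbered pairs, and the highest other among them gave 0 genes and 3 probe sets. Since the brain arrays were taken as paired by number, the real split there is 1 of 8, too few for this test to exclude chance. Chance cannot be excluded for the exon difference between tissues, where 1 probe set was called and 14 of 100 splits gave as many, the highest 38. For genes 0 differences were called, so that all 100 splits gave as many by construction, the highest 286, and the count tests nothing. The splits with many calls point to a structure of the samples, which can be genotype itself. The split with 286 kept the genotypes apart for all 4 cord arrays of a group and for 3 of 4 brain arrays, so the knockout effect in cord can itself give such calls, while that with 38 kept 2 of 4 in each.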

How the results depend on the processing

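Leaving out both brain arrays of number 3, leaving out the 4 cord arrays rich in muscle genes, the muscle covariate, the restriction to genes changed by under 0.5, and the block, scaling and left-out arrays for the lists were chosen after seeing the data.

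Named results mostly kept direction and side of the threshold. Over all alternatives, 372 of 417 values at gene level in brain did, 1049 of 1231 in cord and 2059 of 2173 between tissues, and for exons 568 of 607, 547 of 633 and 365 of 380. The Epb4.1l2 difference did in 7 of 28. The rest were weaker, apart from 3 that reversed: Ankar in cord without a floor (-0.051), and between tissues Foxc1 (0.21) and Btg2 (-0.021) with the floor at the 75th percentile. The cause was not tested for these, nor for the counts below unless said.

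A minimum change of 1 left 10, 36 and 518 genes (brain, cord, tissues) and 150, 189 and 4745 probe sets, by its construction. For the difference of the effects, genes called were 4 with pseudocount 64, 1 without a floor, 11 with the floor at the 75th percentile, 1 with means over probe sets and 34 after quantile normalization. Probe sets called for it were 0 with pseudocount 1, without a floor, with means, after quantile normalization and with the block, 3 with pseudocount 64 and 434 with diffSplice. Exon calls were 489 in cord without a floor and 25837 between tissues with the higher floor, where fewer probe sets were tested. The correlations of brain and cord were 0.312 (genes) and 0.119 (exons) without a floor. Quantile normalization called 1620 genes and 1755 probe sets in cord. DiffSplice called 460 probe sets in brain and 2854 in cord.

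With the arrays of 1 tissue or genotype alone, fewer samples gave 24 genes and 192 probe sets in brain, 200 probe sets in cord and 25444 between tissues. The replicate block gave 78 probe sets and 11 targets in brain and 30 probe sets in cord, where numbers do not pair the arrays. Without both brains of number 3 there were 10 genes and 0 probe sets for the difference and 187 probe sets in brain. Without the cords rich in muscle genes there were 100 genes and 111 probe sets in cord. For the difference there were 1 gene and 2 probe sets, and between tissues 27048 probe sets. All 820 genes kept their direction, with a median size of 0.491 against 0.498. They had been called with the same arrays, and 724 of them were separated, which fixes their direction in any subset. That agreement is therefore no independent check of the arrays rich in muscle genes. In genes changed by under 0.5, 389 probe sets were called in cord.

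An estimated correlation left 0 lists called in brain, cord and difference (5, 7 and 7 at the preset one) and 1 between tissues (11). Fry in one direction called 0 in brain, 9 in cord, 4 for the difference and 19 between tissues, and fry in mixed directions 5 in brain, 15 in cord, 3 for the difference and 23 between tissues.

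Leaving out each array in turn gave 28 to 45 genes in brain, 420 to 1231 in cord, 0 to 18 for the difference and 7487 to 9437 between tissues. For exons it gave 216 to 273, 332 to 889, 0 to 3 and 29665 to 42927. Lists called were 4 (without wild type brain 4) to 9 (without wild type brain 3) in brain, 7 to 9 in cord, 3 (without double knockout brain 3) to 13 (without wild type brain 3) for the difference and 9 to 12 between tissues. The correlations were 0.35 to 0.447 and 0.133 to 0.202. Signal limits the results to probe sets above the floor of 6.73 (log2).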

Other observations

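The tests of imprinted genes and of level against exon changes were chosen after the results were seen.

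Imprinted genes, expressed from 1 parental copy, were among those with a changed level. In double knockout brain Mest rose by 0.67 (adjusted p = 0.0029), and Usp29 (-0.84, adjusted p = 0.00591), Impact (-0.65, adjusted p = 0.00604) and Zim3 (-0.78, adjusted p = 0.0356) fell. In cord Ube3a rose by 0.66 (adjusted p = 0.00506), and Impact (-0.99), Nap1l5 (-0.86), D7Ertd715e (-0.97) and Usp29 (-0.75) fell. Zim3 and Usp29 lie 53 and 54 genes from Nova2. As a list of 39 tested, imprinted genes were not called by camera of limma in brain (mean 0.02, adjusted p = 0.861), cord (-0.07, adjusted p = 0.705), their difference (adjusted p = 0.426) or between the wild type tissues (adjusted p = 0.93).

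The hypothesis that level changes are more frequent among imprinted genes stays open. Of the 39 genes 7 were called by limma in either tissue, where random lists held 2.09 on average (one-sided permutation p = 0.0039), but the list was written after 9 of its members, all 7 among them, had been seen. With the 9 taken out, 0 of 30 were called, which follows from that choice and tests nothing. An earlier version, with 5 taken out, gave 2 of 34 (random mean 1.86, permutation p = 0.557).

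Genes changed in both tissues often held called probe sets: Mtap2 had 20 of 35 probe sets called in both, and Dlg3 3 of 28. Among genes changed by 0.5 or more, apart from Nova1 and Nova2, 18 of 27 called in both tissues (66.7%) held a called probe set in cord, against 88 of 338 called in cord and not in brain (26%; two-sided Fisher exact p = 2.77e-05). The exon index is a probe set's value minus its gene's level, so any probe set that does not follow its gene changes its index when the level changes. Changed probe sets in turn move the level. Calls of levels and of exon indices are thus tied by construction, and the test cannot show whether exon changes go with level changes. The level changes of the first set were also larger (median 0.901 against 0.617).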
